A study of Mus musculus with 4 samples.

How the data were processed

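RNA was sequenced from lung T helper 2 (Th2) cells of mice of the C57BL/6 strain that had received papain, a plant protease that provokes allergic airway inflammation, in a chronic schedule. Per the labels, lungs were digested with collagenase and DNase, and live cells positive for CD4 and for T1/ST2, the receptor for interleukin-33 encoded by Il1rl1, were sorted. Since Il1rl1 was a sort marker, its level is no finding here. The 4 samples fall into 2 genotypes of 2 samples each: Gata3(fl/fl), in which Gata3 carries sites that Cre recombinase can cut, and Klrg1Cre Gata3(fl/fl), which also carries a Cre recombinase named for Klrg1. The first is called control and the second Klrg1Cre below. The labels do not say whether the samples came from separate mice, so the p-values measure the spread between these samples, which may be technical.

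Reads were aligned with STAR and processed in Partek against mouse genome build mm9, per the submitters' processing notes, which give no versions. No coordinates are given, because the genome annotation used here was of another build; it served only to look up gene symbols, of which 11868 of 11883 matched a current symbol, 4 an older one and 11 none. The data are 1 table of the authors' own comparison, with 1 row per gene for 11883 genes and no column for a single sample. Per the file headers, its group means stand under the names WT and ILC2 deficient, the second referring to group 2 innate lymphoid cells (ILC2). WT was taken as control and the other as Klrg1Cre, because the genotype without Cre is the control; the labels do not state this link. The deposited group means are in CPM, read counts scaled to the total of each library. The deposited signal per gene, a column of total counts, equalled 2 times the sum of both deposited means in all 11883 rows and was not used further. The deposited ratio was the quotient of the deposited means in all 11883 rows, and the deposited fold change is the same ratio with a sign. The deposited p-values are the authors', from a model that the sources used here do not name, and the deposited adjusted p-values equalled a Benjamini-Hochberg adjustment of them over all 11883 genes. An offset of 0.0001 CPM had been added to every mean, so a gene at that value is a gene listed at 0; this held for 38 genes in Klrg1Cre and 17 in control.

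No test between the genotypes was run on the group means, because a table of means holds no spread. Fold changes and p-values are therefore the authors', and a gene is said to have risen or fallen only where their adjusted p was below 0.05 over all genes, or where an adjustment of their p over a gene list alone gave a value below 0.05, which is then stated. The adjustment over a list alone was not corrected for the number of lists, so such a call is weaker than one over all genes. Direction is Klrg1Cre relative to control throughout. The plan made before the data were examined had been edgeR on counts, with the authors' values as its fallback; the fallback applied.

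The depth of each library was worked out from the steps of the deposited means. For many genes a mean of 2 libraries in CPM can be written in only 1 way as whole reads of both libraries, and 1 pair of library totals per group made this hold to within 1e-09 reads. These totals were 26019065 and 14564426 reads for the Klrg1Cre libraries and 33379572 and 31961572 for the control libraries. The mean was split in this way for 5820 genes (49.0%) in Klrg1Cre and 5581 (47.0%) in control, and for 5351 genes (45.0%) in both. The others were left as means. For these no split into whole reads was found, possibly because they hold fractions of reads, or the mean was above 20000 CPM and was not tried. The split was tested on simulated means of 11883 genes, where it recovered 100% of the genes with whole reads, made 0 wrong recoveries and gave 0 genes with fractional reads a split. The simulated fractions were drawn at random between 0 and 1, which real fractions need not be, so these counts do not cover other kinds of fraction. Which library of a group is its first or second sample is unknown, so libraries are called the larger and the smaller of their group. Because under 95% of the genes were recovered, no count model was fitted. As a check, limma 3.58.1 in R 4.3.3 was run with a trended variance on log2(CPM + 1) of the 4242 recovered genes with a mean of at least 1 CPM. Its p-values had a Spearman correlation of 0.998 with the authors' p-values across genes, which are not independent replicates. Values were also simulated for these 4242 genes, of which 200 were changed. There, limma called 77.5% of 2-fold changes with 6.06% false calls, and 99.5% of 4-fold changes with 2.93% false calls. Every simulated gene had the same noise between libraries beyond counting, whereas real genes differ in it. These rates therefore do not give the power in the real data, and a gene not called may still have changed 2-fold.

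Before the data were examined, 31 gene lists were fixed: 15 of T cell programmes, 4 of RNA quality or stress and 12 of markers of T cells and other cell types. For the 28 lists with at least 3 measured members, the median log2 ratio with its 95% interval from the order of the members, and the number of members past the threshold, are given. As descriptions, the median was placed among the medians of 10000 random lists of equal size matched on mean expression in 20 bins. Members with an unadjusted p below 0.05 were counted per direction and compared with all other genes by a two-sided Fisher's exact test, adjusted over the lists. Both treat genes as independent, which genes of 1 programme are not, so their p-values are too small. Genes named in the text were fixed by rule: Gata3 and Klrg1; per direction, up to 15 genes past the threshold with at least 5 CPM in a group, filled to 10 by the smallest p where fewer than 5 passed; all Th2 cytokines; and up to 4 members of each other list by the smallest p, with the most abundant member of the quality and cell type lists. Predicted genes and antigen receptor segments were left out of the first choice. A condition that both samples of a group lie on the same side of the others could not be applied to group means. Other genes named were chosen after their values were seen: further list members, and the genes of families defined by symbol. For a gene listed at 0 in a group, the list median used a floor of 3 reads over that group's libraries, 0.0739 CPM in Klrg1Cre and 0.0459 CPM in control.

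Alternatives were a threshold of 0.1, unadjusted p-values, a minimum mean of 1 or 5 CPM, pseudocounts of 0.1, 1 and 5 CPM, and centring on the median of all genes. Scaling to the listed genes other than Rn45s, limma on the recovered libraries and leaving out each recovered library in turn were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.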

Results

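The transcriptomes of lung Th2 cells from papain-treated control and Klrg1Cre mice were compared, 2 samples per genotype. The question was how these cells differ when mice with floxed Gata3 also carry Klrg1Cre. Gata3 encodes the transcription factor that specifies Th2 cells and ILC2. The headers call the group taken as Klrg1Cre ILC2 deficient, and no group carried Klrg1Cre without floxed Gata3. Effects of Gata3 loss in Th2 cells, of a lack of ILC2 and of the Cre allele itself therefore cannot be told apart. Library totals worked out from the deposited means were 26019065 and 14564426 reads for Klrg1Cre and 33379572 and 31961572 for control. In the authors' deposited table, Rn45s, the precursor of ribosomal RNA, held 67.1% of the Klrg1Cre reads and 51.4% of the control reads. The other genes listed held 18.2% and 17.8%, and reads outside the table made up the remaining 14.7% and 30.8%. The median log2 ratio of all genes was 0.01.

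Gata3 itself had a deposited mean of 293.9 CPM in Klrg1Cre and 221.4 CPM in control, a 1.33-fold higher value with an unadjusted p of 0.0115 that did not pass adjustment (adjusted p = 0.551). Reads from exons outside a floxed segment can remain after recombination, and Cre acts only in cells that have expressed it, so this gene-level mean does not check the labels. Klrg1, which encodes an inhibitory lectin-like receptor of differentiated lymphocytes and gives the Cre its name, had a deposited mean of 4.19 CPM in Klrg1Cre against 48.4 CPM in control, 11.5-fold lower. Its adjusted p in the authors' deposited table was 0.0701, above the threshold. The recovered libraries held 1.38 and 7.003 CPM in Klrg1Cre and 42.0 and 54.9 CPM in control. Without the smaller Klrg1Cre library the log2 ratio of Klrg1 was -5.13, and without the larger one -2.79, against -3.53 with both.

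In the authors' deposited table, 7 of 11883 genes passed an adjusted p of 0.05, of which 3 rose and 4 fell in Klrg1Cre. The genes that rose were Matn2, encoding the matrix protein matrilin-2, Nkg7, encoding a protein of cytotoxic granules, and Sema4a, encoding a semaphorin with roles in T cell costimulation. Their deposited means were 7.45 against 0.665 CPM for Matn2 (11.2-fold, adjusted p = 0.0112), 51.2 against 12.8 CPM for Nkg7 (4.02-fold, adjusted p = 0.0112) and 38.9 against 15.1 CPM for Sema4a (2.58-fold, adjusted p = 0.0180). The recovered libraries for Nkg7 held 58.7 and 43.8 CPM in Klrg1Cre and 11.2 and 14.3 CPM in control. The genes that fell were Itgae, encoding the integrin chain CD103, the trefoil factor gene Tff1, the interferon-stimulated gene Ifi27l2a and the transcriptional regulator gene Trerf1. Itgae had a deposited mean of 42.8 CPM against 150.9 CPM in control, 3.53-fold lower (adjusted p = 0.00949). Tff1 was 5.40-fold lower at 3.20 against 17.3 CPM (adjusted p = 0.0112) in the same table. Ifi27l2a was 2.21-fold lower at 77.6 against 171.2 CPM, and Trerf1 2.14-fold lower at 26.8 against 57.3 CPM, with deposited adjusted p of 0.0164 and 0.0316.

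Further genes had small p-values in the authors' deposited table without passing its adjustment. Among those with higher means in Klrg1Cre were Nfkb1, encoding an NF-kappaB subunit, at 111.8 against 61.1 CPM (adjusted p = 0.0635), and Itgb1, encoding integrin beta-1, at 56.8 against 22.04 CPM (adjusted p = 0.0701). Lmna, Anxa2, F2r, Perp and Nmur1, the last encoding the neuromedin U receptor, had deposited ratios of 1.91, 1.86, 1.90, 3.51 and 3.22, with adjusted p between 0.0701 and 0.0980. Among those with lower means, the eosinophil-attracting chemokine gene Ccl24 was listed at 17.8 against 42.7 CPM (adjusted p = 0.0635) and Penk, encoding proenkephalin, at 10.6 against 26.3 CPM (adjusted p = 0.0980). Jcad, Rln3 and N4bp1 had deposited means 2.62-fold, 3.01-fold and 1.95-fold lower, with adjusted p from 0.0701 to 0.0980. At an unadjusted p below 0.05 the deposited table held 843 genes, 442 with higher and 401 with lower means, where 594 would be expected by chance.

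**Figure D1:**
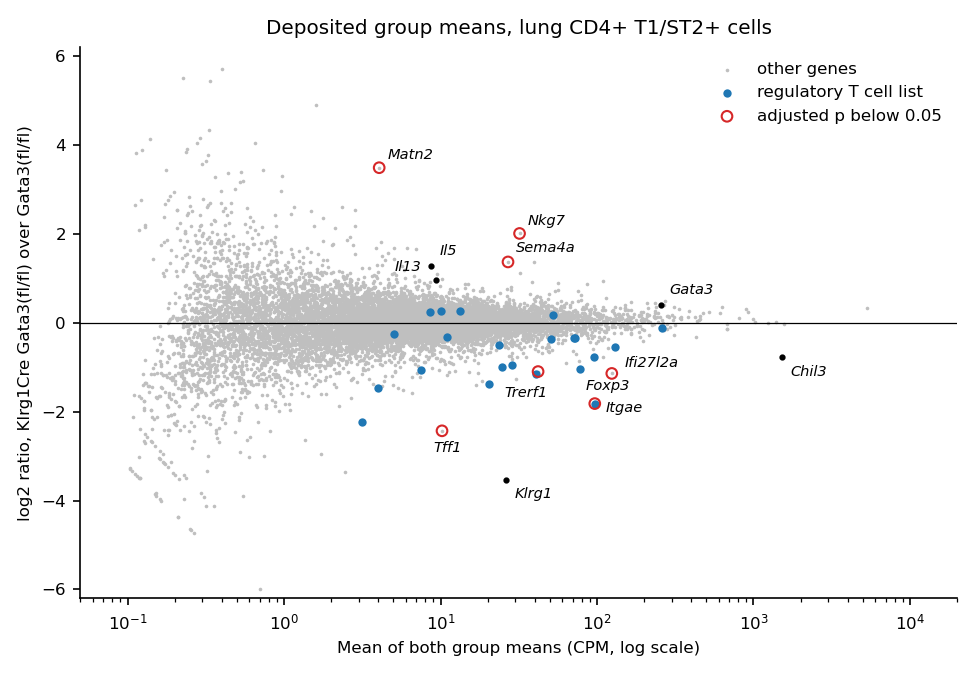
Log2 ratio of the deposited group means, Klrg1Cre over control, against the mean of both group means in CPM (log scale), with 1 point per gene listed above 0 in both groups. Red circles mark the 7 genes with an adjusted p below 0.05, blue points the regulatory T cell list, and black points other genes named; Rn45s lies beyond the right edge and 1 gene beyond the lower edge is drawn on it.

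Genes of regulatory T cells, the Foxp3-expressing CD4 cells that restrain immune responses, had lower means in Klrg1Cre. In the authors' deposited table, 18 of 22 measured list members had lower means, and 1 of them, Itgae, fell with adjustment over all genes. Adjusted over the list alone, 9 members fell and 0 rose. Besides Itgae these were the lineage transcription factor gene Foxp3 (50.6 against 104.6 CPM, 2.07-fold lower), Ikzf2, Ikzf4, Lrrc32, Itgb8, Tnfrsf9, Izumo1r and Gpr83. Deposited means for Izumo1r, encoding folate receptor 4, were 25.3 against 56.2 CPM, and those for Gpr83 were 1.11 against 5.20 CPM. The median log2 ratio of the list was -0.52 (95% interval -1.07 to -0.26), below all 10000 random lists, and 12 members had lower means at an unadjusted p below 0.05 against 0 with higher means (Fisher's exact test, adjusted p = 2.5e-11). Il10, Nrp1, Swap70 and Socs2, also on the list, had higher deposited means without passing any test. Of the 9 members with recovered libraries, 5 had both Klrg1Cre libraries below both control libraries and 0 had both above. Of all 5351 recovered genes, 978 had both below and 1034 both above. Together these were 37.6% of the recovered genes, where 33.3% would be expected by chance with 2 libraries per group. The median of the 9 recovered list members was -0.48 on the log2(CPM + 1) scale, and -0.31 without the larger Klrg1Cre library.

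Activation and inhibitory receptors, a list that shares Ctla4, Tigit, Entpd1, Il2ra, Tnfrsf4, Tnfrsf9 and Tnfrsf18 with the regulatory T cell list, had lower means in 16 of 18 measured members in the authors' deposited table. Adjusted over the list alone, 6 of 18 members fell and 1 rose, and 0 passed adjustment over all genes. The members that fell were Klrg1, Tnfrsf9, Cd38, Cd101, Pdcd1lg2 and the costimulatory receptor gene Icos, whose deposited means were 80.8 against 136.9 CPM. Pdcd1, encoding the inhibitory receptor PD-1, rose over the list alone, with deposited means of 270.6 against 198.3 CPM. The authors' adjusted p for Pdcd1 over all genes was 0.599. Its recovered libraries held 265.6 and 275.5 CPM in Klrg1Cre and 167.1 and 229.6 CPM in control, so the control libraries were far apart. The median log2 ratio was -0.52 (95% interval -0.81 to -0.31), and 9 members had lower means at an unadjusted p below 0.05 against 1 higher (Fisher's exact test, adjusted p = 2.7e-08). For the 12 members with recovered libraries the median was -0.58, and -0.27 without the smaller control library.

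Interferon-stimulated genes, which are induced by type I or type II interferon, also had lower means. Of 29 measured members in the authors' deposited table, 25 were lower in Klrg1Cre, 1 fell with adjustment over all genes (Ifi27l2a) and 4 fell with p adjusted over the list alone. Besides Ifi27l2a these were Ifit3 at 4.42 against 9.63 CPM, Isg15 at 5.61 against 10.3 CPM and Rtp4 at 5.50 against 10.1 CPM. The median log2 ratio was -0.36 (95% interval -0.58 to -0.24), and 10 members had lower means at an unadjusted p below 0.05 against 0 higher (Fisher's exact test, adjusted p = 1.8e-07). The size of this difference rested on 1 library: for the 8 members recovered per library the median was -0.42, but -0.13 without the smaller Klrg1Cre library and -0.86 without the larger one.

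Of the Th2 cytokines and effector proteins, 9 of 14 were listed in the authors' deposited table and 0 passed adjustment over all genes. Adjusted over the list alone, Il5 and Il13, which encode the cytokines that drive eosinophilia and mucus production, rose, and Penk fell. Il5 had deposited means of 12.4 against 5.08 CPM, 2.43-fold higher (adjusted p = 0.00518 over the list alone and 0.289 over all genes). Its recovered libraries held 8.92 and 15.8 CPM in Klrg1Cre and 5.003 and 5.16 CPM in control. The log2 ratio of Il5 was 1.28, and 0.81 without the smaller Klrg1Cre library. Il13 had deposited means of 12.4 against 6.33 CPM, 1.96-fold higher (adjusted p = 0.00502 over the list alone and 0.265 over all genes), and recovered libraries of 11.3 and 13.5 against 6.68 and 5.98 CPM. For Il4 the deposited means were 2.60 against 2.26 CPM, for Areg 3.83 against 2.25 CPM and for Calca 18.4 against 10.1 CPM. For Il6 they were 1.21 against 0.826 CPM, for Il10 9.30 against 7.92 CPM and for Tnfsf11 6.81 against 7.77 CPM. None of these genes passed either adjustment, while Calca had an unadjusted p of 0.0304 in the authors' comparison. The median log2 ratio of the list was 0.55 (95% interval -0.19 to 0.97), and 3 members had higher means at an unadjusted p below 0.05 against 1 lower (Fisher's exact test for higher means, adjusted p = 0.0254). With a pseudocount of 1 the median was 0.28.

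Th2 regulators and receptors showed no common direction in the authors' deposited table. Of 27 measured members, 0 passed adjustment over all genes; adjusted over the list alone, Plac8 rose (44.4 against 20.5 CPM) and Icos fell. Ecm1, encoding an extracellular matrix protein needed for Th2 cells to leave lymph nodes, had deposited means of 27.9 against 40.8 CPM without passing either adjustment. Their median log2 ratio was -0.06 (95% interval -0.19 to 0.29).

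**Figure D2:**
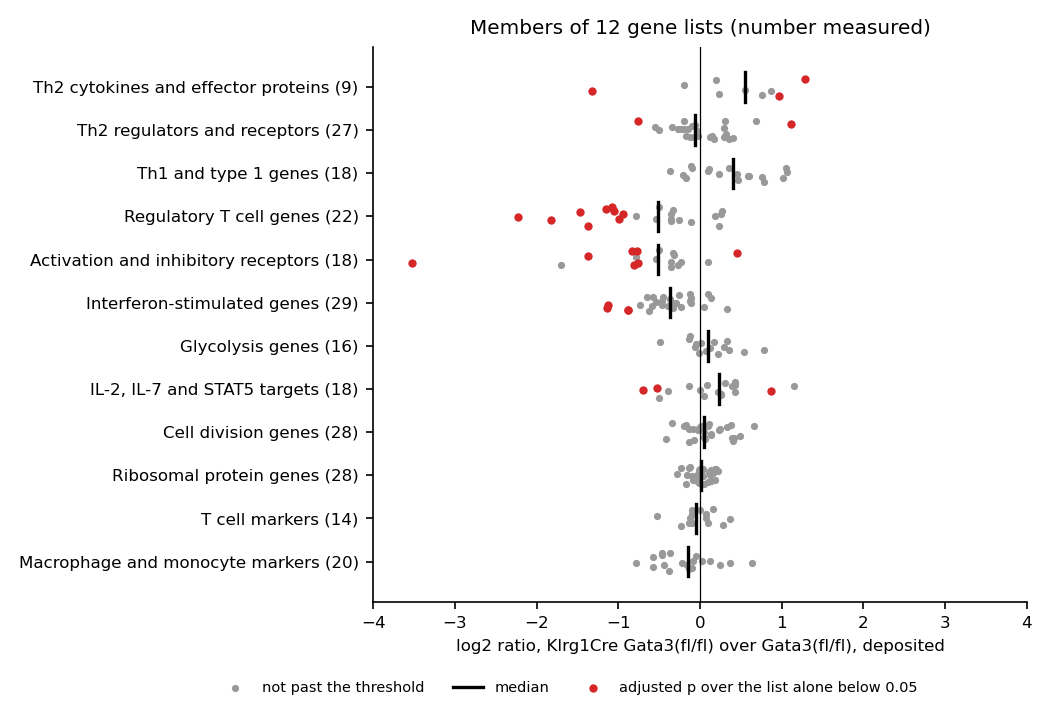
Log2 ratio of the deposited means, Klrg1Cre over control, for each measured member of 12 gene lists (points, spread vertically within a list to avoid overlap), with the list median as a black bar and members with an adjusted p over the list alone below 0.05 in red. The regulatory T cell and activation receptor medians lie at -0.52 and the T cell marker median at -0.05; Marco, listed at 0 in control, is counted in its list but not drawn.

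Of the Th1 and type 1 genes in the authors' deposited table, 0 of 18 passed either adjustment, while 5 had higher means at an unadjusted p below 0.05 against 1 lower (Fisher's exact test for higher means, adjusted p = 0.0037). Examples were the chemokine receptor gene Cxcr3 at 18.0 against 10.5 CPM, Ccl5 at 5.07 against 2.41 CPM, Ccl4 at 3.21 against 1.58 CPM, Il18r1 at 12.1 against 7.94 CPM and Il12rb1 at 30.2 against 22.1 CPM. The master regulator gene Tbx21 had deposited means of 2.86 against 1.90 CPM and Ifng 0.578 against 0.278 CPM. Over the list, the median log2 ratio was 0.41 (95% interval -0.10 to 0.75), but 0.065 over the members with a mean of at least 5 CPM and 0.12 with a pseudocount of 5, so it rested on genes with low means.

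Of 9 cytotoxic genes listed by the authors' deposited table, Nkg7 rose with adjustment over all genes and Ctsw fell with p adjusted over the list alone (33.5 against 47.5 CPM), while Gzma was listed at 0.268 against 0.858 CPM and Tnfsf10 at 18.5 against 21.5 CPM. Their median log2 ratio was -0.02, or 0.055 over members with a mean of at least 5 CPM. Of 11 Th17 genes in the table, Il21 rose over the list alone (1.69 against 0.533 CPM) and Tmem176a and Tmem176b fell (2.07 against 4.33 and 4.74 against 9.06 CPM), with a median of -0.11, or -0.20 over members with a mean of at least 5 CPM. Of 13 follicular helper genes, Il21 and Pdcd1 rose and Icos, Sh2d1a, Cxcr5 and P2rx7 fell over the list alone, with a deposited median of -0.10. At an unadjusted p below 0.05, 4 had lower and 3 higher means, so members moved both ways (Fisher's exact test, adjusted p = 0.00502 for lower and 0.0620 for higher means). Of 16 naive and central memory genes, Klf2, encoding a factor that promotes exit from tissue (4.88 against 2.08 CPM), and Foxp1 (32.2 against 21.2 CPM) rose and Il7r, the interleukin-7 receptor gene (56.1 against 91.3 CPM), fell over the list alone, with a median of -0.16, or -0.38 over members with a mean of at least 5 CPM. Of 13 tissue residency genes, Itgae fell over all genes and Prdm1 (21.6 against 31.1 CPM) over the list alone, with a deposited median of -0.16 (Fisher's exact test for lower means, adjusted p = 0.0430).

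Of 18 targets of interleukin-2, interleukin-7 and STAT5 signalling in the authors' deposited table, Pim2 rose (19.3 against 10.5 CPM) and Il7r and Prdm1 fell over the list alone. At an unadjusted p below 0.05, 5 had higher deposited means and 3 lower (Fisher's exact test for higher means, adjusted p = 0.0037). Their median log2 ratio was 0.24 (95% interval -0.13 to 0.43), above 9997 of 10000 random lists, and became 0.15 both over members with a mean of at least 5 CPM and with a pseudocount of 5. Of 16 glycolysis genes, 0 passed either adjustment and 5 had higher deposited means at an unadjusted p below 0.05 against 0 lower (Fisher's exact test for higher means, adjusted p = 0.0037), among them the glucose transporter gene Slc2a1 at 18.1 against 12.4 CPM, Hk2 at 3.57 against 2.07 CPM, Pfkp at 64.4 against 51.2 CPM and Eno1 at 181.5 against 147.9 CPM. The median of this list was 0.10 (95% interval -0.06 to 0.33). None of the 28 cell division genes passed an adjustment or an unadjusted p of 0.05, with a deposited median of 0.05 (95% interval -0.03 to 0.23) and, as an example, Ccnb2 at 11.5 against 8.21 CPM. None of the 19 genes of lipid uptake and storage passed either, with a median of 0.05, and Pparg was listed at 19.2 against 15.01 CPM.

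**Figure D3:**
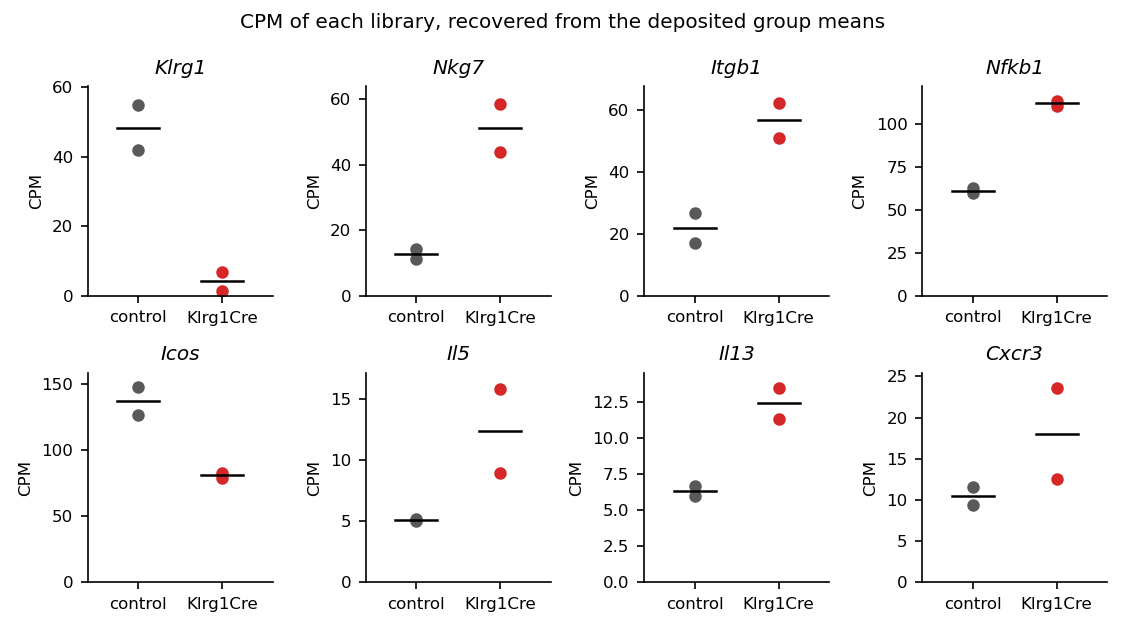
CPM of each of the 4 libraries for 8 genes whose deposited group means could be split into whole reads of both libraries; points are libraries, bars the deposited group means, and each axis starts at 0. For Klrg1 the Klrg1Cre libraries lie at 1.38 and 7.003 CPM and the control libraries at 42.0 and 54.9 CPM.

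Within the lists of RNA quality and stress, single genes differed. The make-up of the libraries differed as well, with Rn45s at 67.1% of reads in Klrg1Cre against 51.4% in control. Reads outside the listed genes made up 14.7% against 30.8%. These differences follow genotype and cannot be separated from it here. In the authors' deposited table, 0 of 28 ribosomal protein genes passed a test, with a median log2 ratio of 0.01 (95% interval -0.04 to 0.11) and the most abundant member, Rplp0, at 655.5 against 561.3 CPM. Of 25 immediate early and dissociation stress genes, Fos (70.2 against 42.3 CPM) and Ier2 (33.3 against 19.7 CPM) rose over the list alone. Hspa1a (0.438 against 4.47 CPM), Nr4a3 and Egr2 fell over it, and the deposited median was 0.09. At an unadjusted p below 0.05, 4 had lower and 3 higher means (Fisher's exact test, adjusted p = 0.0430 for lower and 0.241 for higher means). Of 15 apoptosis genes and p53 targets, Perp and Aen rose and the pro-apoptotic genes Pmaip1 (8.02 against 14.8 CPM) and Bcl2l11 (9.95 against 17.1 CPM) fell over the list alone, as did Trp53inp1 (21.3 against 35.5 CPM), with a median of 0.01. Of 13 mitochondrially encoded genes, 0 were listed.

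Markers of T cells were close between genotypes: in the authors' deposited table, 0 of 14 passed either adjustment, the median log2 ratio was -0.05 (95% interval -0.13 to 0.16), and the most abundant, Lck, had 243.1 against 259.3 CPM. Of 17 ILC2 markers, some of which Th2 cells also express, 0 passed adjustment over all genes; over the list alone Nmur1 rose (7.73 against 2.40 CPM) and Klrg1, Arg1 (53.9 against 98.5 CPM) and Il2rb (93.2 against 122.1 CPM) fell, with a deposited median of -0.24 (95% interval -0.39 to -0.10). Of 20 macrophage and monocyte markers, 0 passed either adjustment, with a median of -0.15 (95% interval -0.44 to 0.02). The most abundant, Chil3, encoding a chitinase-like protein of alternatively activated macrophages, had deposited means of 1124 against 1932 CPM (adjusted p = 0.599), and Lyz2, encoding lysozyme, 395.9 against 364.0 CPM. Of 12 dendritic cell markers, 0 passed either adjustment; H2-Ab1 had deposited means of 50.7 against 38.9 CPM, and the median was 0.24, or 0.38 over members with a mean of at least 5 CPM and 0.05 with a pseudocount of 5.

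Markers of the remaining cell types were also listed in the authors' deposited table, and 0 passed either adjustment. The median log2 ratios were 0.39 for 3 mast cell and basophil markers, 0.49 for 7 eosinophil and neutrophil markers, -0.67 for 5 B cell markers, -0.31 for 10 lung epithelial markers, 0.55 for 5 endothelial and stromal markers and 0.79 for 3 red blood cell and platelet markers. The mast cell and basophil figure rests on Slc18a2, Hdc and Gata2, with deposited means of 0.584 against 0.0470 CPM for Gata2. These medians rest on genes with low means: with a pseudocount of 1 they became 0.23 for mast cells and basophils, 0.33 for eosinophils and neutrophils, -0.19 for B cells, -0.12 for epithelium, 0.42 for endothelium and stroma and 0.15 for red blood cells and platelets. Of the CD8 T cell markers only Cd8b1 was listed, at 3.07 against 2.93 CPM, and of the NK cell markers Gzma and Prf1, the latter at 0.0880 against 0.259 CPM.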

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

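The scaling to other genes, the library-level fits and the leaving out of libraries were chosen after seeing the data. Against 7 genes in the authors' deposited table, 22 had an adjusted p below 0.1, 843 an unadjusted p below 0.05, and 16 an adjusted p below 0.05 when only genes with a mean of at least 5 CPM were adjusted for, since fewer genes are then tested; that filter gained 10 calls and left Matn2 untested. With limma on 4242 recovered genes, 7 passed (4 higher, 3 lower), adjusted over these genes rather than over all 11883. Among them was Nkg7, the 1 gene of the authors' 7 that was recovered. The remaining limma calls had not passed the authors' adjustment, so the equal counts do not mean that the same genes were called. The other authors' calls could not be checked per library. Leaving out 1 library, with the lone library assumed to vary like the other group, gave 58 without the larger Klrg1Cre library, 64 without the smaller, 0 without the larger control library and 1 without the smaller (262 and 181 at an unadjusted p below 0.05); the cause was not tested. Klrg1 was at -3.53 on the log2 scale and passed with the 5 CPM filter (-3.53, adjusted p = 0.0421, against 0.0578 with 1 CPM and 0.0701 with none). It was at -2.54 with a pseudocount of 5, which shrinks low genes, and from -5.13 to -2.79 with 1 library left out. Pseudocounts shrank the medians of lists with low members. With pseudocounts of 1 and 5 the median of Th2 cytokines was 0.28 and 0.15, of Th1 genes 0.30 and 0.12, of mast cell and basophil markers 0.23 and 0.11, of eosinophil and neutrophil markers 0.33 and 0.15, of endothelial and stromal markers 0.42 and 0.10, and of interferon-stimulated genes -0.33 and -0.21. Over members with a mean of at least 5 CPM, the Th1 median was 0.065, that of naive and central memory genes -0.38, that of Th17 genes -0.20, that of dendritic cell markers 0.38, that of STAT5 targets 0.15 and that of cell division genes 0.03. With a pseudocount of 5, medians were 0.05 for dendritic cell markers, 0.15 for STAT5 targets, 0.02 for cell division genes, and -0.07 for both naive and tissue residency genes. The sign of 3 medians near 0 turned: cytotoxic genes were at 0.055 with the 5 CPM filter, and scaling to other genes gave -0.02 for apoptosis genes and -0.01 for ribosomal protein genes. Medians of regulatory T cell genes were -0.47 with a pseudocount of 5 and -0.43 with the 5 CPM filter. With 1 library left out, medians of recovered members ran from -0.86 to -0.13 for interferon-stimulated genes, -0.58 to -0.27 for activation receptors, -0.70 to -0.31 for regulatory T cell genes and 0.32 to 0.43 for Th1 genes.

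Pseudocounts, filters and scaling leave the sign of nearly every single gene fixed by construction, so they say nothing about its direction; leaving out libraries can turn it. Of 78 named genes with recovered libraries, 40 had an unadjusted p below 0.05, of which 0 changed sign when a library was left out. Of the others, 11 did. A small p from these same libraries leaves little room for a change of sign, so the count of 0 is no separate check of direction. Scaling to the listed genes other than Rn45s moved all log2 ratios by -0.03. The edgeR scalings, DESeq2, limma-voom and correlation-adjusted set tests were not run. There were no sample columns, and whole reads were recovered for only 45.0% of genes. No paired analysis was possible because the table has no sample columns and the recovered libraries carry no replicate number. Under 0.0739 CPM in Klrg1Cre and 0.0459 CPM in control, the value of 3 reads over a group, a level cannot be told from 0.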

Other observations

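All families and tests in this part were chosen after the values were seen, and 16 families of genes defined by symbol were compared. In the authors' deposited table, 6 of 17 genes of the TNF receptor superfamily had lower means in Klrg1Cre at an unadjusted p below 0.05 and 0 had higher means (Fisher's exact test, p adjusted over the families 0.000103). They were Tnfrsf9, Tnfrsf4 (70.6 against 121.0 CPM), Tnfrsf18 (106.7 against 155.3 CPM), Tnfrsf1b, Tnfrsf8 and Tnfrsf22, of which the first 3 were on the regulatory T cell list. Of the 9 family members with recovered libraries, 2 had both Klrg1Cre libraries below both control libraries and 2 had both above. Gimap genes, which encode GTPases that sustain lymphocyte survival, had 3 of 8 members lower and 0 higher at an unadjusted p below 0.05 in the deposited table (adjusted p = 0.00753), led by Gimap7 at 10.8 against 23.7 CPM. Among the interferon-inducible GTPase genes (Gbp, Irgm, Igtp, Iigp and Tgtp), 6 of 16 were lower and 0 higher at an unadjusted p below 0.05 (adjusted p = 0.000103), with Tgtp1 at 2.29 against 6.15 CPM and Gbp7 at 36.1 against 52.7 CPM.

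Single genes of other families had higher means: Plxdc2 was listed at 4.83 against 0.828 CPM and Plxdc1 at 4.93 against 2.39 CPM in the authors' deposited table, Anxa2 at 72.8 against 39.2 CPM and the calcium-binding S100a11 at 51.7 against 34.6 CPM. At an unadjusted p below 0.05, 3 of 17 genes with symbols starting with Sema or Plx had higher means. So did 2 of 8 annexins and 2 of 9 S100 proteins, and 0 members of these families had lower ones. The Sema and Plx group takes in Plxdc1 and Plxdc2, which encode plexin-domain-containing proteins rather than plexins. None of these families passed the adjustment over families (Fisher's exact test for higher means, adjusted p = 0.167 for each). For Plxdc2 the recovered libraries held 4.92 and 4.74 CPM in Klrg1Cre and 0.749 and 0.907 CPM in control.

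The lower means of regulatory T cell genes were weighed against scaling, a single library and cell composition. Scaling or the larger share of ribosomal RNA would lower T cell markers alike. Their median was instead -0.048, with a 95% interval whose lower bound of -0.13 lies above the list's -0.52. With each library left out in turn, the median of the 9 recovered members of 22 stayed negative, between -0.70 and -0.31. Its sign thus did not rest on 1 library, though its size varied. Itgae, Gpr83, Izumo1r and Tnfrsf9 were not recovered and could not be checked in this way. A smaller share of regulatory T cells among the sorted cells, lowering their genes alike, may account for Ikzf2, Ikzf4, Lrrc32 and Izumo1r, which lie within 0.11 of Foxp3 (-1.05) on the log2 scale, but 10 of 21 members, among them Ctla4, Capg and Nrp1, had ratios above that of Foxp3 by over 2 standard errors, so the list as a whole was not lowered alike. Itgae and Gpr83 were lower than Foxp3 by over 2 standard errors, a count of 2 of 21 members that had first been set as the bound against this explanation; with 0.779 such members expected by chance that bound was wrong, and the smallest p adjusted over the members was 0.175. Fewer regulatory T cells and lower expression in each of them (list median -0.52) cannot be told apart from bulk means, which do not show how much of each gene came from other cells, and an effect of the genotype on such cells stays a hypothesis.

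The lower mean of Chil3 may reflect fewer macrophages, reads shared with a near copy, or a changed state of myeloid cells whose RNA came through a gate for CD4 and T1/ST2. Fewer macrophages would lower their other abundant transcripts alike, but Lyz2, Cd68, Fcgr3, Ctss, Apoe and Fn1, the 6 other markers with a mean of at least 20 CPM, had a median log2 ratio of 0.016 against -0.78 for Chil3, and 4 of the 6 lay above it by over 2 standard errors. A shift of reads to Chil4 would raise that gene, but its log2 ratio was -0.72. A changed state stays open: Ccl24, another product of alternatively activated macrophages, had a log2 ratio of -1.26, which bulk means cannot tie to a cell type, and neither Chil3 nor Ccl24 passed the adjustment over all genes.

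Klrg1 lay further below control than the regulatory T cell genes. A fall of both in equal proportion would put Klrg1 near the log2 ratio of Foxp3 (-1.05, standard error 0.26), but even the highest Klrg1Cre library over the lowest control library gave -2.58. This does not exclude a shared cause, since loss of cells that express Klrg1, some of them regulatory T cells, could remove most Klrg1 and only part of Foxp3. A Cre construct that alters the Klrg1 transcript, and loss of such cells (log2 ratio -3.53 over the whole gene), cannot be told apart, because a mean per gene does not show which part of the gene lost reads. The standard errors used in these tests were read back from the authors' p-values with 9.71 degrees of freedom, as estimated by limma, and were 1.07 times those of limma at the median of 2688 recovered genes.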
